A study of Rattus norvegicus with 17 samples.

How the data were processed

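Gastrocnemius muscle was sampled from healthy rats, from rats bearing a tumor, and from rats bearing a tumor and given chemotherapy, all on the control diet per the sample titles. Per the labels, total RNA was depleted of ribosomal RNA and made into stranded libraries. The labels do not name the tumor or the chemotherapy agent.

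The deposited table held raw counts of reads per gene for 17 libraries, with no normalisation by the authors. The submitters' processing notes name CASAVA 1.9, Trim Galore 0.4.1, FastQC 0.11.4, TopHat2 2.0.10 and Bowtie2. The genome build, the annotation and the counting program are not given in the sources used here. Even values made up 46.0% to 59.6% of counts from 1 to 10. In library 4, with the highest share, 244, 394, 239 and 366 entries had counts of 1, 2, 3 and 4. Such an excess of even counts arises when the 2 mates of a read pair are counted one by one. Shares at the low end of the range do not show this by themselves. The table had 32883 entries, of which 388 carried no gene name and were left out. The 32495 named entries held 29826 distinct names, and 192 names stood on more than 1 entry. Such entries were kept apart, because the table holds nothing that tells them from one another. The 4 largest cells were deposited with 3 significant digits, and 2 gene names had been turned into dates.

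Libraries 11 and 12, both from the chemotherapy group, had alignment names that differed by 1 letter. Their counts differed by a chi-square of 2.05 per degree of freedom. Repeat sequencing of 1 RNA with mates counted one by one would give at most 2. The value lies just above that, so some further difference between the 2 libraries is possible. The next closest of the pairs within a group, libraries 13 and 14, gave 6.07, and pairs across groups were not compared. The counts of libraries 11 and 12 were therefore summed into 1 sample, called library 11 below, which left 16 samples: 5 healthy, 5 tumor and 6 tumor with chemotherapy. The plan fixed before the data were examined had 17 libraries, so this is a departure from it, and the fit with 17 was run as an alternative. The alignment names also end in 1 of 2 suffixes, MB or VM, whose meaning is not given. MB stood on 4 healthy libraries and on libraries 11 and 12, and VM on 1 healthy library (library 5), all 5 tumor libraries and the 5 other chemotherapy libraries. A suffix term in a fit therefore rests on healthy library 5 and the summed library 11, each the only sample of its group with its suffix.

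Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filterByExpr filter (minimum count 10) and robust quasi-likelihood fits. All 16 samples entered 1 model with a mean per group and 13 residual degrees of freedom. Values of p were adjusted by Benjamini and Hochberg's method over the 11856 genes tested, and a gene was called at an adjusted p below 0.05. Fold changes are log2, with a standard error (SE) taken as the size of the fold change over the square root of the F statistic. Levels are CPM, counts scaled by library size and TMM factor, given as mean ± SD.

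Before the data were examined, 44 gene lists were fixed, and the 39 with at least 5 measured members were tested. The list test was camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the lists of each comparison. Camera was run again with the correlation estimated from the data, and fry tested whether a list moved one way on its own. For each list the number of members called over all genes and the number called when adjusted over the list alone were counted. A list score per sample, the mean over members of log2 CPM minus the mean of the gene, was compared by a two-sided exact permutation test. The smallest exact p that 5 against 5 samples can give is 0.00794, and 6 against 5 samples can give 0.00216. Listed genes with no matching name in the table are not analysed here, and 7 ribosomal protein and 4 oxidative phosphorylation entries share a name with other entries.

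Genes are named by a rule fixed before the data were examined. It takes the 5 highest and the 5 lowest called genes with a mean of at least 5 CPM and an assigned symbol, or those with the smallest p where fewer were called. It adds the 3 members with the smallest p of each of the 6 lists with the smallest p. It adds the top member of each other list with at least 3 calls, and 10 genes fixed by name. Some genes picked in this way are not reported here. Clone names beginning with AC and 6 digits were also treated as placeholders, which was decided after the values were seen. A gene named outside the rule is said to be so where it is named.

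Alternatives planned before the data were examined were DESeq2 size factors, total counts only, no filter, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom and a fit of only the 2 groups compared. The others planned were a run without the 20 most abundant genes, 1 surrogate variable from sva 3.50.0 and leaving out each library in turn. Chosen after the data were seen were the fit with libraries 11 and 12 apart, the suffix as a term, only the VM libraries, and a fit without healthy libraries 1, 3 and 4. The overlap of comparisons that share the healthy group was set against 50 simulations and against 20 splits of the healthy libraries. The procedure was tested on simulated counts with the groups and depths of these samples. Of the genes simulated with a 2-fold change, 28 of 47 were recovered for tumor against healthy, 28 of 48 for chemotherapy against healthy and 35 of 50 for chemotherapy against tumor. False calls there were 11 of 138, 5 of 136 and 5 of 135. The simulated genes varied independently, without the library differences shared across genes that the real samples show. The false calls and the recovered shares therefore do not describe the error rate or the power in the real samples. A 1.5-fold change was recovered for 5 of 48, 11 of 50 and 8 of 48 genes.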

Results

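RNA from the gastrocnemius, a hindlimb muscle, was sequenced from 5 healthy rats, 5 tumor-bearing rats and 6 tumor-bearing rats given chemotherapy, counting libraries 11 and 12 as 1 sample. Total counts averaged 9011000 in healthy, 7657950 in tumor and 7596360 in chemotherapy samples, and ranged from 3023899 to 15777909 per deposited library. The totals did not differ detectably (exact permutation p = 0.595 for tumor against healthy, 0.680 for chemotherapy against healthy, 0.948 for chemotherapy against tumor). The 20 most abundant genes held 40.8% ± 3.26 of the counts (SD, n = 5) in healthy, 36.2% ± 2.44 (n = 5) in tumor and 36.0% ± 1.33 (n = 6) in chemotherapy samples. Exact permutation p was 0.0397 for tumor against healthy and 0.0216 for chemotherapy against healthy.

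The first principal component of the 1000 most variable genes held 48.4% of the variance and the second 7.54%. Healthy libraries 1, 3 and 4 lay at 27.7, 33.0 and 42.0 on the first component, apart from healthy library 2 at -10.4 and healthy library 5 at 7.18. Chemotherapy library 11 lay at 4.81 and the 5 other chemotherapy samples between -28.1 and -6.36. The tumor samples spread from -20.9 to 19.8. Correlation across genes averaged 0.941 between healthy libraries, 0.955 between tumor libraries, 0.959 between chemotherapy samples and 0.925 between healthy and chemotherapy samples. Genes are not independent replicates in these correlations.

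**Figure D1:**
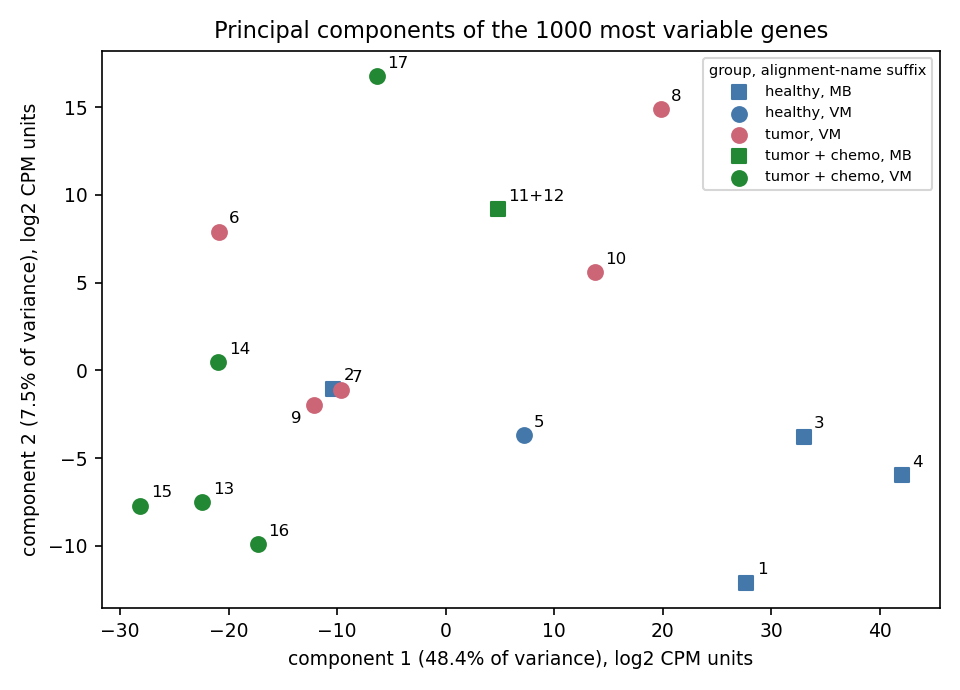
Principal components of log2 CPM over the 1000 most variable genes, 1 point per sample, colored by group and shaped by alignment-name suffix. Healthy libraries 1, 3 and 4, all MB, lie at 27.7, 33.0 and 42.0 on component 1, above the 13 other samples. Healthy library 2 and chemotherapy library 11, also MB, lie at -10.4 and 4.81, and tumor library 8, VM, at 19.8.

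The series asks how a tumor, without or with chemotherapy, alters the muscle, and the first comparison set tumor-bearing against healthy rats (n = 5 and 5). Slow-fiber contractile genes were called higher as a list: all 11 measured members had positive fold changes, with a median log2 fold change of 0.68 (camera adjusted p = 1.24e-06, 0.784 with an estimated correlation). Tnnt1, the slow skeletal troponin T, averaged 886 ± 207 CPM in tumor and 401 ± 228 in healthy muscle (log2 fold change 1.14 ± 0.29 SE). Atp2a2, the calcium pump of slow fibers and heart, averaged 1852 ± 364 against 1097 ± 283 CPM, and Myh7b, a slow-type myosin heavy chain, 30.5 ± 10.3 against 15.4 ± 4.62 CPM. None of the 11 members was called over all genes, and 7 were called higher when adjusted over the list alone. The list's score was higher in all 5 tumor samples than the healthy median (difference 0.716, exact permutation p = 0.0238, adjusted p = 0.31 over 39 lists). The list's call was lost with the suffix as a term (adjusted p = 0.0574).

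Extracellular matrix genes were called lower as a list in tumor-bearing rats: 27 of 34 had negative fold changes, with a median log2 fold change of -0.42 (camera adjusted p = 3.76e-06, 0.869 with an estimated correlation), and 2 of the 5 tumor samples had a score above the healthy median (exact permutation p = 0.222). Col4a1, a basement membrane collagen, averaged 260.0 ± 92.0 CPM in tumor and 483 ± 121 in healthy muscle. Col3a1, a fibrillar collagen, averaged 1266 ± 502 against 2695 ± 1100 CPM, and Eln, which encodes elastin, 19.5 ± 5.78 against 38.4 ± 15.8 CPM. Macrophage markers were called lower too, with 16 of 18 negative and a median of -0.43 (adjusted p = 0.00196, 0.869 with an estimated correlation), at an exact permutation p of 0.143 for the score. Among them Itgam averaged 8.32 ± 2.06 against 14.9 ± 7.51 CPM and Cd163 27.8 ± 4.84 against 41.3 ± 8.0. All 6 class II antigen presentation genes had negative fold changes (median -0.50, adjusted p = 0.0301, 0.869 with an estimated correlation), at an exact permutation p of 0.0635 for the score. Adjusted over the list alone, 4 matrix genes and 1 macrophage marker were called lower and no class II gene. The matrix list lost its call with 1 surrogate variable (adjusted p = 0.887), pointed up with the suffix as a term (0.945) and was not called without healthy libraries 1, 3 and 4 (0.344). The macrophage call was lost in the same 3 fits (adjusted p = 0.475, 0.128 and 0.344), and the class II call with 1 surrogate variable and without healthy libraries 1, 3 and 4 (0.478 and 0.17). Without healthy library 2, without healthy library 5 or without tumor library 6, the class II list was not called (adjusted p = 0.0666, 0.0823 and 0.0606).

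Fast-fiber and glycolytic genes were called lower as lists, with no member called over all genes. Of 14 fast-fiber genes, 11 had negative fold changes (median log2 fold change -0.21, adjusted p = 0.0184, 0.869 with an estimated correlation), and so had 17 of 24 genes of glycolysis and glycogen (median -0.20, adjusted p = 0.0184, 0.784 with an estimated correlation). The scores had an exact permutation p of 0.119 for fast-fiber and 0.0556 for glycolysis genes. Ckm, the muscle creatine kinase, averaged 28260 ± 10100 CPM in tumor and 48340 ± 16500 in healthy muscle. Myoz1 averaged 2896 ± 701 against 4727 ± 1330 CPM, and Mylpf, a fast myosin light chain, 12050 ± 2910 against 18350 ± 6060. In tests adjusted over the list alone, 1 fast-fiber gene was called lower, and 1 glycolysis gene higher and 2 lower. The fast-fiber call was lost without healthy library 1, healthy library 2 or tumor library 6 (adjusted p = 0.0513, 0.101 and 0.0563). It was also lost with no filter, with the suffix as a term and without healthy libraries 1, 3 and 4 (adjusted p = 0.06, 0.323 and 0.131). The glycolysis call was lost without healthy library 1 or 2 (adjusted p = 0.0878 and 0.0666), and without the 20 most abundant genes (0.103). Nor did it hold with the suffix as a term or without healthy libraries 1, 3 and 4 (adjusted p = 0.0985 and 0.23).

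All 5 red blood cell genes had negative fold changes (median log2 fold change -1.06, camera adjusted p = 0.00306, 0.784 with an estimated correlation), at an exact permutation p of 0.0238 for the score (adjusted p = 0.31). Hba-a2, an alpha globin, averaged 73.0 ± 27.5 CPM in tumor and 173 ± 74.3 in healthy muscle, Hbb 168 ± 57.7 against 353 ± 137 and Hbb-bs 10.5 ± 3.74 against 21.1 ± 8.08. All 5 replication-dependent histone genes were also negative (median -1.01, adjusted p = 0.00486, 0.784 with an estimated correlation), at an exact permutation p of 0.0952 for the score. Hist1h2bo averaged 3.94 ± 2.11 against 13.3 ± 11.6 CPM, H2ax 6.78 ± 1.27 against 13.5 ± 7.03 and Hist2h2aa3 2.76 ± 1.80 against 5.47 ± 2.56. Most replication-dependent histone messages carry no poly(A) tail, and the share of counts on small noncoding RNA genes was 1.42% ± 0.662 in tumor and 2.40% ± 1.18 in healthy samples (exact permutation p = 0.143). Adjusted over the list alone, 4 red blood cell and 4 histone genes were called lower. The histone call was lost with 1 surrogate variable and with the suffix as a term (adjusted p = 0.475 and 0.171). Without healthy libraries 1, 3 and 4 neither list was called (adjusted p = 0.131 for red blood cell and 0.975 for histone genes). The VM libraries alone hold 1 healthy sample, library 5, so the fit with them settles none of the 8 lists called here. In it matrix, macrophage and red blood cell genes were called lower (adjusted p = 0.026, 0.0205 and 0.0205). Class II, glycolysis and histone genes were not called (adjusted p = 0.0764, 0.848 and 0.542), and slow-fiber and fast-fiber genes turned (0.976 and 0.929).

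No single gene passed the threshold between tumor-bearing and healthy rats with edgeR, where 2134 of 11856 genes had an unadjusted p below 0.05 (1053 higher, 1081 lower) and 593 would by chance. DESeq2 called 13 genes higher and 50 lower of the 1705 genes its filtering kept, and limma-voom called 0. The smallest adjusted p was 0.211, shared by the 9 genes named here. Socs3, an inhibitor of cytokine signaling, averaged 3.17 ± 1.11 CPM in tumor and 10.2 ± 2.89 in healthy muscle (log2 fold change -1.70 ± 0.32 SE). Col4a5 was at -1.01, Tmem205 at -0.91 and Lrrc41 at -0.77 on the log2 scale. Esm1, an endothelial secreted protein, averaged 10.8 ± 3.11 against 4.0 ± 1.86 CPM (1.47 ± 0.315 SE). Cep250 was at 0.95, Tra2a at 0.89, Plekha1 at 0.82 and Ctnnal1 at 0.75. The groups did not overlap for 118 genes (1.0%), where chance gives 0.794%. Without healthy library 2, edgeR called 245 genes higher and 259 lower. Without healthy library 5 it called Tnnt1 higher and Col4a5 lower.

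The markers of muscle atrophy fixed by name showed no detectable change in tumor-bearing rats. Fbxo32 and Trim63, the muscle ubiquitin ligases atrogin-1 and MuRF1, had log2 fold changes of -0.04 ± 0.31 and 0.05 ± 0.12 (SE; adjusted p = 0.960 and 0.848). Mstn, which encodes the growth inhibitor myostatin, was at 0.43 ± 0.24 and Foxo1 at -0.27 ± 0.21. Cdkn1a was at 0.43 ± 0.39, Pdk4 at -0.27 ± 0.46, Ppargc1a at 0.27 ± 0.21, Myh7 at 0.55 ± 0.26 and Col1a1 at -0.08 ± 0.64, none called. Gdf15 did not pass the expression filter. The 31 lists not called here ran from complement (adjusted p = 0.0579) to pericyte and smooth muscle markers (adjusted p = 0.953). Myogenesis and satellite cell genes had an adjusted p of 0.0664, and their score lay below the healthy median in all 5 tumor samples (difference -0.22, exact permutation p = 0.00794, adjusted p = 0.31). Scaled by total counts only, that difference was -0.096 (exact permutation p = 0.135), with 1 tumor sample above the healthy median, while camera called the list lower (adjusted p = 0.0361). The complement list was called lower without healthy library 1, tumor library 8 or tumor library 10 (adjusted p = 0.0331, 0.0101 and 0.0207). The myogenesis list was called lower without healthy library 3, healthy library 4 or tumor library 7 (adjusted p = 0.0289, 0.0454 and 0.0348). Oxidative phosphorylation genes were called lower without healthy library 4 or tumor library 6, 9 or 10 (adjusted p = 0.0454, 0.0061, 0.0178 and 0.0191), and ribosomal proteins without tumor library 9 or 10 (0.0244 and 0.0198). So were acute phase genes without healthy library 5 or tumor library 8 (0.0317 and 0.0174), and fibroblast markers without tumor library 8 (0.0411). Clock genes were called higher without healthy library 5 or tumor library 9 (0.0463 and 0.0199), and adipocyte markers without tumor library 7 or 9 (0.0348 and 0.0322). Leaving out tumor library 9 gave 3 lists higher, and leaving out tumor library 7 or healthy library 5 gave 2, against 1 with all libraries. Leaving out healthy library 2 gave 4 lists lower in place of 7.

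**Figure D2:**
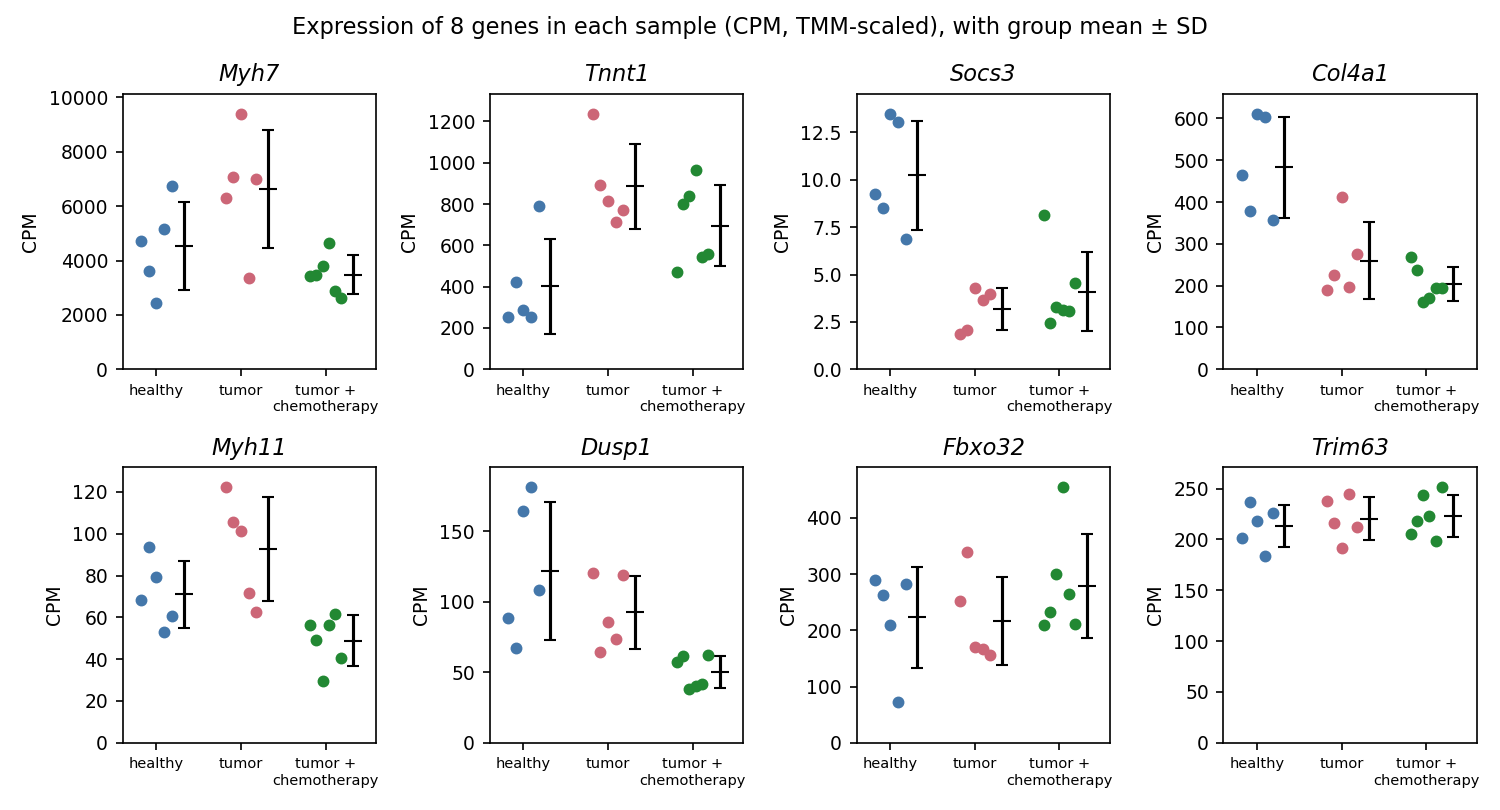
Expression of 8 genes in CPM for each of the 16 samples by group, with group mean and SD beside the points. Myh7 and Tnnt1 are slow-fiber genes, Myh11 a smooth muscle gene, and Fbxo32 and Trim63 atrophy ligases. Trim63 averaged 213 CPM in healthy, 220.4 in tumor and 223 in chemotherapy samples.

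Chemotherapy-treated tumor-bearing rats against healthy rats (n = 6 and 5) addressed the tumor and the treatment together. The calls of single genes given here and in the next 6 paragraphs all ended with 1 surrogate variable, with the suffix as a term or without any 1 of 6 of the libraries, named further below. Of all 11856 genes tested, 865 were called higher and 760 lower, and the counts of list members are to be read against that. Of the 39 lists, extracellular matrix had the smallest p and the most genes called lower, though not the largest median fall: 15 of 34 genes were called lower and none higher, 32 had negative fold changes, and the median log2 fold change was -0.76 (camera adjusted p = 1.53e-09, 0.97 with an estimated correlation). The score had an exact permutation p of 0.0173 (adjusted p = 0.113). Col4a1 averaged 205 ± 40.9 CPM against 483 ± 121 in healthy muscle (log2 fold change -1.24 ± 0.21 SE, adjusted p = 0.0261), with all 6 samples below all 5 healthy ones. Col4a2 fell from 212 ± 46.9 to 99.3 ± 22.4 CPM and Col5a2 from 226 ± 58.2 to 123 ± 28.0. Of 17 fibro-adipogenic and fibroblast markers, 5 fell and 12 were not called (median -0.50, adjusted p = 0.00559, 0.97 with an estimated correlation), at an exact permutation p of 0.0325 for the score (adjusted p = 0.141). The 5 were Cd34, a progenitor surface marker, at 50.6 ± 7.55 against 105 ± 34.0 CPM, Smoc2, Cxcl14 and, outside the naming rule, the growth factor receptors Pdgfra and Pdgfrb.

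Markers of pericytes and smooth muscle, the wall of vessels, fell in 6 of 14 members with 8 not called (median log2 fold change -0.49, adjusted p = 0.0183, 0.97 with an estimated correlation), at an exact permutation p of 0.00649 for the score (adjusted p = 0.0633). Cspg4, the pericyte proteoglycan NG2, averaged 30.8 ± 6.76 CPM against 62.1 ± 13.2 in healthy muscle, and Notch3 33.3 ± 9.82 against 72.5 ± 17.9. Des, which encodes desmin and is abundant in muscle fibers too, fell from 8117 ± 2590 to 3809 ± 947 CPM. Of 19 endothelial markers 2 rose and 1, Tie1, fell (45.1 ± 5.60 to 28.8 ± 4.68 CPM), and the list was not called (adjusted p = 0.542). The 2 that rose were Emcn and Fabp4, named after their values were seen. Among tests adjusted over the list alone, 20 matrix, 5 fibroblast, 7 smooth muscle and 1 endothelial genes were lower, and 2 endothelial genes higher. With 1 surrogate variable the matrix list was not called (adjusted p = 0.242) and the fibroblast list pointed up (adjusted p = 0.887), and the fibroblast call was lost without healthy libraries 1, 3 and 4 (adjusted p = 0.0516), while smooth muscle stayed called and lower in each alternative scaling, filter and sample choice.

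Histone and small noncoding RNA genes were among the lowest genes. Vault, a small noncoding RNA, averaged 11.9 ± 4.79 CPM with chemotherapy and 52.2 ± 24.9 in healthy muscle (log2 fold change -2.10 ± 0.46 SE), and Hist1h2bo 3.40 ± 1.84 against 13.3 ± 11.6 (-1.98 ± 0.47). Hist1h2ail1 was at -1.82, and 2 of the 33 entries named Metazoa_SRP, the RNA of the signal recognition particle, were at -1.87 and -1.58. Entries with a repeated name cannot be told apart by it, so these values are uncertain. All 5 histone genes were negative, Hist1h2bo and Hist2h2aa3 were called, and H1f5 was at -1.08 ± 0.38 (median -1.08, list adjusted p = 0.028, 0.97 with an estimated correlation), at an exact permutation p of 0.0238 for the score (adjusted p = 0.116). All 5 red blood cell genes were negative with none called (median -0.88, adjusted p = 0.025, 0.97 with an estimated correlation, exact permutation p = 0.0628 for the score), Hba-a1 at -1.08, Hbb at -1.06 and Hbb-bs at -0.84. When adjusted over the list alone, 5 histone and 3 red blood cell genes were lower. Small noncoding RNA genes took 1.01% ± 0.308 of counts with chemotherapy and 2.40% ± 1.18 in healthy samples (exact permutation p = 0.0260). The histone call was lost without healthy library 4 (adjusted p = 0.0535), and with 1 surrogate variable that list pointed up (adjusted p = 0.606). It was also lost with the suffix as a term and without healthy libraries 1, 3 and 4 (adjusted p = 0.0956 and 0.859). The red blood cell call was lost with no filter, with 1 surrogate variable and without healthy libraries 1, 3 and 4 (adjusted p = 0.0953, 0.279 and 0.0765). In the fit with 1 healthy sample, the VM libraries alone, matrix, fibroblast and smooth muscle genes were called lower (adjusted p = 5.17e-10, 0.000535 and 0.00139), and histone and red blood cell genes were not (0.302 and 0.0787).

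Genes of mitochondrial energy metabolism were called in both directions, and these member counts fell to 0 in the fits that called no gene. Of 52 nuclear-encoded oxidative phosphorylation genes 11 rose, 5 fell and 36 were not called, and of 23 tricarboxylic acid cycle genes 5 rose and 1 fell. Sdhd, a subunit of succinate dehydrogenase and a member of both lists, rose from 230.3 ± 62.4 to 396 ± 62.0 CPM. Of 29 fatty acid oxidation genes 2 rose and 1 fell, with Acadm, a medium-chain acyl-CoA dehydrogenase, up from 245 ± 102 to 486 ± 102 CPM. Of 19 regulators of mitochondrial biogenesis 3 rose and 1 fell, among them Tfb2m, a mitochondrial transcription factor, from 11.7 ± 5.23 to 25.8 ± 8.47 CPM. In glycolysis and glycogen metabolism 1 of 24 genes rose, Fbp2, the muscle fructose bisphosphatase (49.9 ± 11.1 to 84.9 ± 16.7 CPM), and 5 fell. In lipid synthesis 1 of 21 rose and 5 fell, including Srebf2, a regulator of cholesterol synthesis (68.2 ± 18.5 to 43.0 ± 6.0 CPM). In insulin, IGF and mTOR signaling 1 of 28 rose and 5 fell, including Tsc2, an inhibitor of mTOR (104 ± 23.3 to 58.8 ± 8.75 CPM). Adjusted over the list alone, higher and lower counts were 14 and 9 for oxidative phosphorylation, 8 and 1 for the tricarboxylic acid cycle, and 3 and 1 for fatty acid oxidation. They were 4 and 2 for biogenesis, 1 and 8 for glycolysis, 2 and 7 for lipid synthesis, and 5 and 5 for insulin signaling. None of these 7 lists was called by camera (adjusted p from 0.0829 for lipid synthesis to 0.883 for oxidative phosphorylation). The oxidative phosphorylation test pointed up with a median of -0.04 and a mean of 0.10. Biogenesis pointed up with a median of -0.04 and a mean of 0.11, and insulin signaling down with a mean of 0.02. The score was higher for oxidative phosphorylation (exact permutation p = 0.00649, adjusted p = 0.0633) and the tricarboxylic acid cycle (0.0173, adjusted 0.113). It was lower for glycolysis (exact permutation p = 0.00649, adjusted p = 0.0633). For the remaining lists the exact permutation p ran from 0.0649 to 0.909. The tricarboxylic acid cycle was called higher without healthy library 1 (adjusted p = 0.0394). Glycolysis was called lower without healthy library 4 or 5 (adjusted p = 0.0325 and 0.0303), and lipid synthesis without healthy library 5 or chemotherapy library 17 (adjusted p = 0.0303 and 0.0239).

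Genes of protein synthesis and breakdown were called in both directions as well, as were 865 genes higher and 760 lower of all 11856 tested. Autophagy, ubiquitin ligase, FoxO and unfolded protein response genes were called at about that share. Of 61 ribosomal protein genes 14 rose and 1 fell (median log2 fold change 0.17, adjusted p = 0.0935), and 1 of the 4 entries named Rpl21 rose from 32.6 ± 15.4 to 74.5 ± 7.20 CPM. Of 38 proteasome subunits 3 rose and 4 fell, with Psmd2 down from 387 ± 50.1 to 273 ± 21.2 CPM. Of 39 autophagy and lysosome genes 3 rose and 3 fell. Of 22 ubiquitin ligase and atrophy genes 1 rose and 2 fell, Fbxo31 among them (97.9 ± 23.6 to 58.5 ± 12.7 CPM). Of 23 FoxO and glucocorticoid targets 2 rose and 1 fell. Of 20 heat shock genes 4 rose and 2 fell, with Hspd1, the mitochondrial chaperonin HSP60, up from 99.0 ± 46.0 to 207 ± 46.8 CPM. Of 25 genes of the unfolded protein response 2 rose and 1, Hyou1, fell, and of 26 genes of myostatin, activin and TGF-beta signaling 1 rose and 1 fell. When adjusted over the list alone, higher and lower counts were 18 and 7 for ribosomal proteins, 3 and 5 for the proteasome, 3 and 3 for autophagy, and 4 and 9 for ubiquitin ligases. They were 3 and 1 for FoxO targets, 4 and 4 for heat shock, 2 and 1 for the unfolded protein response, and 1 and 1 for myostatin signaling. None of these 8 lists was called by camera (adjusted p from 0.0935 to 0.883), and the FoxO test pointed down with a median of 0.02. The ribosomal list was called higher without healthy library 3, healthy library 4 or chemotherapy library 15 (adjusted p = 0.0423, 0.0192 and 0.0250). So it was with 1 surrogate variable (adjusted p = 5.97e-13), the suffix as a term (0.00423) and total counts only (0.0286). It was also called higher without healthy libraries 1, 3 and 4 (1.31e-06), but not with an estimated correlation (0.97).

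The atrophy ligases Fbxo32 and Trim63 were not called, at log2 fold changes of 0.32 ± 0.30 and 0.07 ± 0.12 (SE). Neither were Mstn at 0.54 ± 0.23, Foxo1 at -0.53 ± 0.20, Cdkn1a at 0.23 ± 0.38, Pdk4 at 0.61 ± 0.44, Ppargc1a at 0.32 ± 0.205, Myh7 at -0.38 ± 0.25 and Col1a1 at -1.04 ± 0.61. Of 14 fast-fiber genes 3 fell, among them Myoz1 (4727 ± 1330 to 3009 ± 537 CPM), and of 11 slow-fiber genes none was called. Of 19 genes of calcium handling 4 fell, with Cacng1, a subunit of the muscle calcium channel, down from 512 ± 131 to 307 ± 26.0 CPM. Of 22 myogenesis and satellite cell genes 5 fell, including Megf10 (13.7 ± 3.19 to 6.30 ± 2.78 CPM), and the list score was below the healthy median in all 6 samples (difference -0.265, exact permutation p = 0.00649, adjusted p = 0.0633). With total counts only that difference was -0.127 (exact permutation p = 0.0996), with 2 samples above the healthy median. Of 21 denervation and neuromuscular junction genes 1 rose, Gadd45a, a stress-induced gene (4.70 ± 1.23 to 10.3 ± 1.87 CPM), and 2 fell. Adjusted over the list alone, 4 fast-fiber, 8 myogenesis and 2 denervation genes were lower, 1 denervation gene was higher, and calcium handling had 5 higher and 6 lower. Camera called none of these 5 lists (adjusted p from 0.156 to 0.883), and the calcium handling test pointed down with a median of 0.04. Without healthy library 5 the slow-fiber list was called higher (adjusted p = 0.0303).

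Immune and stress genes gave few calls. Of 19 immediate early genes 2 fell, Dusp1, a MAP kinase phosphatase (122 ± 49.0 to 50.2 ± 11.4 CPM), and Jun (129 ± 24.4 to 86.7 ± 22.8 CPM), and Fos was at -0.64 ± 0.25. That list missed the threshold (adjusted p = 0.0522, 0.97 with an estimated correlation). It was called lower with no filter and with total counts only (adjusted p = 0.00936 and 0.0224). With only the 2 groups compared and without the 20 most abundant genes it was called lower too (adjusted p = 0.0286 and 0.0281). Of 32 interferon response genes 2 rose, including Ifi44 (5.42 ± 1.23 to 9.67 ± 2.37 CPM), and 1 fell. Of 18 macrophage markers 2 rose, Fcgr2b and Aif1, and of 15 complement genes 1 rose, Cd55. Of 18 acute phase, IL-6 and STAT3 genes 1 fell, Socs3, of 10 Schwann cell and nerve markers Ngfr fell, of 18 clock genes Nr1d1 fell and of 17 cell cycle genes Ccnd1 fell. Of 12 adipocyte markers Fabp4 rose, of 20 metallothionein and oxidative stress genes Sod2 rose, and of 26 DNA damage genes Gadd45a rose and 1 other fell. Fcgr2b, Aif1, Cd55, Ngfr and Sod2 were named after their values were seen. No mast cell (7) or class II (6) gene was called. In tests adjusted over the list alone, the counts of these lists were unchanged but for cell cycle, with 0. The 12 other lists in this set were not called either, from adipocyte markers (adjusted p = 0.122) to cell cycle (adjusted p = 0.968). The test and the median differed in sign for mast cell markers (up, median -0.07), metallothioneins (up, -0.07), Schwann cell markers (down, 0.24) and cell cycle (down, 0.09). Without 1 of healthy libraries 1, 2 and 5 or chemotherapy libraries 11, 14 and 17, the immediate early list was called lower (adjusted p = 0.0179, 0.0462, 0.0303, 0.0220, 0.0221 and 0.0263). Without chemotherapy library 17 the class II list was called lower (adjusted p = 0.0382).

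Over all genes, 865 were called higher and 760 lower in chemotherapy than in healthy samples (edgeR; 1669 and 348 scaled by total counts only), 358 and 116 of them with a log2 fold change of at least 1 in size, and 1567 of the 1625 were protein coding. The highest were Pin4, a peptidyl-prolyl isomerase, at 15.4 ± 4.24 against 3.43 ± 2.89 CPM (log2 fold change 2.33 ± 0.47 SE, adjusted p = 0.0261), Thrsp at 2.02 ± 0.65, Cep290 at 2.0 ± 0.55, Cdo1 at 1.86 ± 0.58 and Hook1 at 1.78 ± 0.47. Library 17 carried much of the rise of Thrsp and Cdo1: without it they were at 0.921 ± 0.409 (adjusted p = 0.119) and 1.192 ± 0.462 (adjusted p = 0.0837). Without healthy library 2, Cep290 was at 2.834. In 474 genes (4.0%) the groups did not overlap, where chance gives 0.433%. The count rested on single libraries. It fell to 0 without healthy library 1, 3 or 4 or chemotherapy library 13, 14 or 15, with 3678, 3480, 3055, 3759, 3502 and 3718 genes at an unadjusted p below 0.05. In those 6 fits the 1625 genes, where tested, all kept their sign, at a median log2 fold change of 0.68 to 0.76 in the reported direction against 0.78 with all samples. Without chemotherapy library 16 it was 261 higher and 268 lower, and without library 17, 577 and 463. Without library 2 it was 2024 and 1775, without library 5, 1236 and 1162, and without library 11, 1505 and 1384. With the suffix as a term no gene was called (993 at an unadjusted p below 0.05), nor with the VM libraries alone (1050), of which 1 was healthy. The median fold change of the 1625 genes in the reported direction was then 0.55 (median SE 0.26) and 0.60 (0.33), with 1625 and 1618 of them keeping their sign. Leaving out healthy libraries 1, 3 and 4 together, chosen after the data were seen, left 0 calls (585), at a median of 0.42 (0.26). DESeq2 called 1407 higher and 1101 lower, and limma-voom 1564 and 880.

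**Figure D3:**
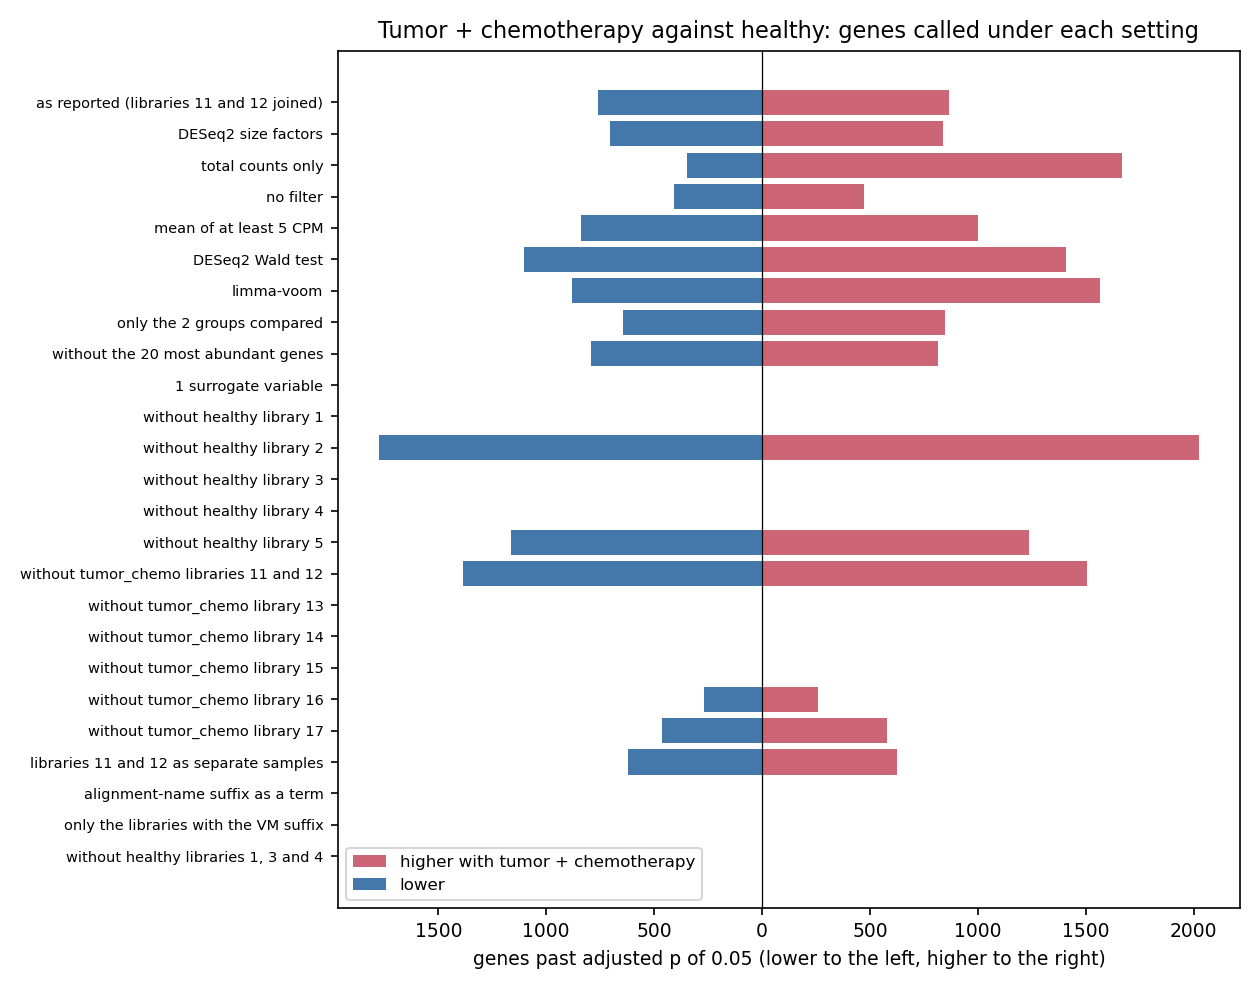
Genes past an adjusted p of 0.05 in chemotherapy against healthy samples under each setting, with genes higher to the right and lower to the left. The bars run from 0 genes, as without healthy library 1, 3 or 4, to 2024 higher and 1775 lower without healthy library 2.

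The fold changes of both comparisons with healthy rats ran alike across genes. The difference of mean log2 CPM between chemotherapy and healthy samples correlated with that between tumor and healthy samples at 0.831 across 11856 genes, and 82.8% of genes had the same sign. The shared healthy group alone gave 0.518 (0.492 to 0.538) and 67.2% in simulations. Those drew each gene independently, so their range leaves out library differences shared across genes and is too narrow for these samples. With different healthy libraries for each comparison the correlation averaged 0.513 (0.016 to 0.670) and the covariance 0.134, against 0.187 with all. Both comparisons set only or mostly VM samples against a healthy group with MB on 4 libraries. Splitting the healthy libraries leaves that in place, so an effect of the tumor cannot be told apart from the suffix here. No gene was called in both, since edgeR called 0 in tumor against healthy (2134 at an unadjusted p below 0.05; 13 higher and 50 lower by DESeq2).

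Chemotherapy-treated against untreated tumor-bearing rats (n = 6 and 5) addressed the treatment, and all of its samples but library 11 carry the VM suffix. Ribosomal protein genes were called higher as a list, by a small amount: 57 of 61 had positive fold changes with a median log2 fold change of 0.19 (camera adjusted p = 1.19e-10, 0.464 with an estimated correlation). Rps23 averaged 223 ± 21.7 CPM with chemotherapy and 170 ± 26.2 without, Rpl34 58.8 ± 7.05 and 46.8 ± 5.07, and Rpl6 249 ± 22.9 and 203 ± 24.2. Their score was above the tumor median in all 6 chemotherapy samples (difference 0.208, exact permutation p = 0.0173, adjusted p = 0.169). No member was called over all genes or adjusted over the list alone. Oxidative phosphorylation genes were called higher as a list, with 37 of 52 positive and a median of 0.08 (adjusted p = 0.00181, 0.77 with an estimated correlation). Their score was above the tumor median in only 2 of the 6 samples (exact permutation p = 0.242), or in all 6 scaled by total counts only (0.203), and no member was called. The list was not called without tumor library 7 or 8 (adjusted p = 0.203 and 0.196). In the VM libraries alone (5 and 5) both kept their calls (adjusted p = 1.27e-06 and 0.0101).

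Pericyte and smooth muscle markers were called lower as a list with chemotherapy: 13 of 14 were negative with a median log2 fold change of -0.31 (camera adjusted p = 6.87e-07, 0.0998 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, averaged 48.9 ± 12 CPM with chemotherapy and 92.6 ± 24.7 without (log2 fold change -0.93 ± 0.20 SE), with all 6 samples below all 5 tumor samples. Acta2, smooth muscle actin, averaged 10.5 ± 4.70 against 22.9 ± 8.52 CPM, and Tagln, a smooth muscle actin-binding protein, 31.0 ± 7.15 against 51.8 ± 8.02. None of the 14 was called over all genes, and 6 were called lower when adjusted over the list alone. The score was below the tumor median in all 6 samples (difference -0.433, exact permutation p = 0.00866, adjusted p = 0.169). The call held with fry (adjusted p = 0.0329), where no other list was called, and with the VM libraries alone (adjusted p = 2.72e-06). Endothelial markers were not called (8 of 19 positive, median -0.09, adjusted p = 0.200), but were called lower without tumor library 10 (adjusted p = 0.0381).

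**Figure D4:**
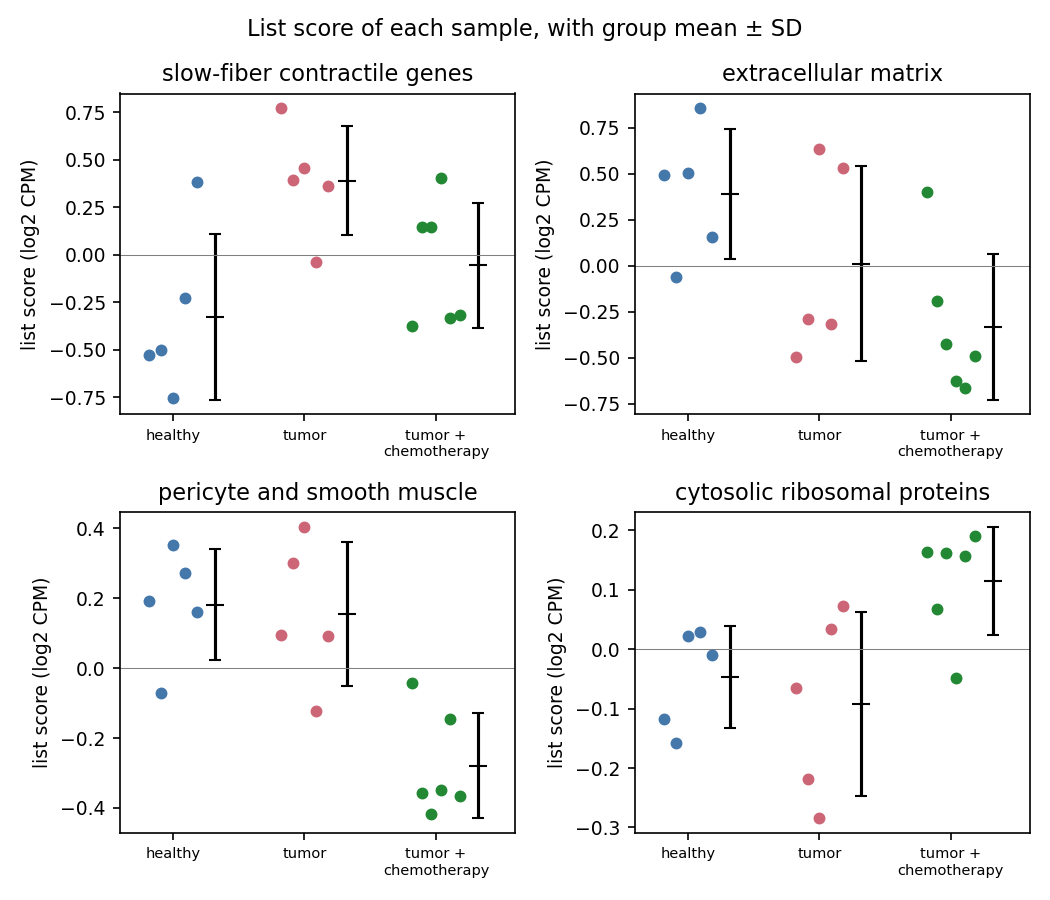
List scores of each sample in log2 CPM for 4 gene lists by group, with group mean and SD beside the points. The smooth muscle score averaged -0.28 with chemotherapy, 0.15 with tumor alone and 0.18 in healthy muscle, and the slow-fiber score -0.05, 0.39 and -0.33.

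Slow-fiber genes were called lower as a list in treated than in untreated tumor-bearing rats: all 11 genes were negative with a median log2 fold change of -0.35 (adjusted p = 3.42e-06, 0.464 with an estimated correlation). None was called over all genes, and 2 were called lower adjusted over the list alone. Myh7, the slow myosin heavy chain, averaged 3474 ± 714 CPM with chemotherapy and 6624 ± 2170 without, Atp2a2 1213 ± 239 and 1852 ± 364, and Tnni1 666 ± 110 and 945 ± 203. Matrix genes (31 of 34 negative, median -0.31, adjusted p = 3.42e-06, 0.76 with an estimated correlation) and fibroblast markers (14 of 17 negative, median -0.32, adjusted p = 0.000176, 0.611 with an estimated correlation) were called lower as lists, with no member called over all genes or adjusted over the list alone. The scores had an exact permutation p of 0.0519 for slow-fiber, 0.21 for matrix and 0.141 for fibroblast genes, with 1, 2 and 1 of 6 samples above the tumor median. Tnc, the matrix glycoprotein tenascin C, averaged 32.5 ± 21.3 against 78.0 ± 54.3 CPM, Col12a1 108 ± 58.3 against 202 ± 105 and Col4a2 99.3 ± 22.4 against 143 ± 50.6. Col22a1, a collagen of the muscle-tendon junction, averaged 26.9 ± 2.71 against 40.1 ± 14.3 CPM, Thbs4 251.6 ± 120 against 434 ± 229 and Fmod 178 ± 118 against 327 ± 144. With 1 surrogate variable the matrix and fibroblast lists were not called (adjusted p = 0.142 and 0.125), and with the VM libraries alone all 3 were (adjusted p = 7.42e-05, 2.93e-10 and 2.72e-06).

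Immediate early and clock genes were called lower as lists with chemotherapy too. Of 19 immediate early genes 14 were negative (median log2 fold change -0.26, adjusted p = 0.000176, 0.464 with an estimated correlation), with Fos at 9.68 ± 3.15 against 19.8 ± 6.06 CPM, Egr1 at 5.11 ± 1.89 against 10.2 ± 2.87 and Dusp1 at 50.2 ± 11.4 against 92.5 ± 26.0. Of 18 clock genes 12 were negative (median -0.28, adjusted p = 0.00132, 0.266 with an estimated correlation). Nr1d1, the clock repressor REV-ERB alpha, averaged 97.7 ± 13.1 against 190.1 ± 66.7 CPM. When adjusted over the list alone, 4 immediate early and 4 clock genes were lower. The time of day of sampling is not in the labels. The scores had an exact permutation p of 0.0801 for immediate early and 0.0152 for clock genes (adjusted p = 0.521 and 0.169). With the VM libraries alone both lists were called (adjusted p = 7.33e-05 and 0.00570).

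Macrophage markers were called higher as a list than in the untreated tumor group (14 of 18 positive, median log2 fold change 0.39, adjusted p = 0.000203, 0.665 with an estimated correlation), as did mast cell markers (6 of 7 positive, median 0.39, adjusted p = 0.0489, 0.673 with an estimated correlation). Libraries 11 and 17 had the highest scores of the 6 (macrophage 0.5059 and 0.4016, others at most 0.1246; mast cell 0.5285 and 0.8123, others at most 0.187), and library 17 also had the highest sums of B and T cell markers. Lipid synthesis genes were called lower (17 of 21 negative, median -0.24, adjusted p = 0.0180, 0.673 with an estimated correlation), as did denervation and neuromuscular junction genes (15 of 21 negative, median -0.20, adjusted p = 0.0358, 0.464 with an estimated correlation). The scores had an exact permutation p of 0.11 for macrophage, 0.197 for mast cell, 0.323 for lipid synthesis and 0.00866 for denervation genes (the last 0.169 adjusted). No member of these 4 lists was called over all genes or adjusted over the list alone. With the VM libraries alone the macrophage, mast cell and lipid synthesis calls were lost (adjusted p = 0.0673, 0.235 and 0.0519). With 1 surrogate variable lipid synthesis and denervation were not called (adjusted p = 0.174 and 0.117), nor was denervation at a mean of 5 CPM or more (0.0634). The mast cell call was lost with DESeq2 size factors, total counts only, no filter and only the 2 groups compared (adjusted p = 0.0516, 0.0502, 0.105 and 0.0824). It was lost with the suffix as a term and without healthy libraries 1, 3 and 4 too (adjusted p = 0.182 and 0.0708). Without tumor library 9 the macrophage call was lost (adjusted p = 0.0572). The lipid synthesis call was lost without library 8, 11 or 14 (adjusted p = 0.193, 0.0586 and 0.0845). The denervation call was lost without library 6, 7, 9, 14 or 17 (adjusted p = 0.0638, 0.0541, 0.0572, 0.105 and 0.134). The mast cell call was lost without library 6, 7, 9, 11, 14 or 17 (adjusted p = 0.198, 0.0618, 0.275, 0.206, 0.0574 and 0.293). The other 27 lists were not called, from the tricarboxylic acid cycle (adjusted p = 0.0975) to the unfolded protein response (adjusted p = 0.999). The tricarboxylic acid cycle was called higher without tumor library 6 (adjusted p = 0.0189), complement without tumor library 8 or 10 (0.000875 and 0.0293) and adipocyte markers without tumor library 8 (0.0097). Class II genes were called higher without tumor library 8 or chemotherapy library 13 (0.0101 and 0.0382), and endothelial markers lower without tumor library 10 (0.0381). Without tumor library 7 or 9 only 2 lists were called higher in place of 4.

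No single gene passed the threshold between treated and untreated tumor-bearing rats with edgeR, where 685 genes had an unadjusted p below 0.05 (233 higher, 452 lower) and 593 would by chance. With limma-voom the count was 0 (691 at an unadjusted p below 0.05), and DESeq2 called 3 lower (826): Fras1, Nr1d1 and Flnc. Fras1, a basement membrane protein, averaged 29.0 ± 2.66 CPM with chemotherapy and 57.2 ± 14 without (log2 fold change -0.99 ± 0.17 SE, edgeR adjusted p = 0.172). Flnc, the muscle filamin, averaged 1504 ± 235 against 2580 ± 558 CPM, and Ccnd1, cyclin D1, 11.2 ± 2.79 against 20.3 ± 4.10. Gadd45g, a stress-induced gene, averaged 19.8 ± 8.72 against 7.27 ± 2.80 CPM (1.49 ± 0.34 SE, adjusted p = 0.441). Gtpbp8 was at 0.66, Haus5 at 0.55, Clcc1 at 0.53 and Myf6, a myogenic regulator, at 0.39. Fbxo32 and Trim63 were at 0.36 ± 0.30 and 0.02 ± 0.12 (SE). Mstn was at 0.10 ± 0.23, Foxo1 at -0.27 ± 0.20, Cdkn1a at -0.20 ± 0.37, Pdk4 at 0.87 ± 0.44, Ppargc1a at 0.05 ± 0.20 and Col1a1 at -0.96 ± 0.61. The groups did not overlap for 57 genes (0.48%), where chance gives 0.433%. Without tumor library 9, edgeR called 3 genes lower: Fras1, Nr1d1 and AABR07015055.1, the last named after its values were seen.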

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

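The sign tests along the within-group axis and against the suffix, and the splits for the ribosomal and smooth muscle lists, were set before their results were seen; the tests with the VM libraries alone, with 1 surrogate variable and of smooth muscle against endothelial markers, and the splits for the counts of genes and lists, were chosen after.

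The 1625 genes called between chemotherapy and healthy samples follow an axis of library differences that also runs within the groups. That axis holds 36.8% of the variance within groups, and 98.5% of the called genes have the sign it gives, against 83.5% of all tested genes. The VM minus MB difference within groups sets only healthy library 5 against healthy libraries 1 to 4, and chemotherapy library 11 against the other chemotherapy samples. Its sign was shared by 95.6% of the called genes. The same share over all tested genes was not computed, so that value does not show that the called genes in particular follow the suffix. With the suffix as a term the median fold change of these genes in the reported direction went from 0.78 (median SE 0.22) to 0.55 (0.26) on the log2 scale, with only the VM libraries, 1 of them healthy, to 0.60 (0.33), and with 1 surrogate variable to 0.23 (0.17), and the calls ended because the folds shrank, and with the suffix and in the VM libraries the SE grew. Of 100 splits of the 11 samples, 3 called as many genes, the real one included (1625, highest other 4384), and 3 gave as many at an unadjusted p below 0.05 (4315, highest other 5618), but these are 2 of 9 counts split and no allowance is made for that, so chance is not excluded, and the splits above the real one move healthy library 2 to the chemotherapy side, which points to a structure of the samples. A difference in sample quality or handling, along the axis or the suffix, may account for many of the calls. The axis is not the suffix alone: among tumor samples, all VM, axis scores ran from -37.6 in library 8 to 33.3 in library 6. Healthy library 2, with MB, was at 24.6, on the side of most chemotherapy samples. Within each group the share of counts on small noncoding RNA genes fell as the axis score rose, except between healthy libraries 1 and 3. That share was 2.37% in tumor library 8 and 0.859% in tumor library 6. It was 3.92% in healthy library 4, at -71.18 on the axis, and 0.812% in healthy library 2. The axis therefore runs along with a measure of library composition, but no test of this was run and its cause is open. The tumor with its treatment stays open and untested as the cause of the difference between the groups along the axis. GC content and transcript length were not analysed here.

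Ribosomal protein genes were called higher as a list with chemotherapy than with tumor alone. The list stayed called with only the VM libraries (adjusted p = 1.27e-06), where the suffix does not vary, and with 1 surrogate variable (adjusted p = 1.09e-22). Over its alternatives in scaling, filter and samples the adjusted p ran from 1.09e-22 to 1.27e-06. The call was lost with an estimated correlation (adjusted p = 0.464). As the suffix is the same in all VM libraries, it cannot account for the difference among them. Other splits of the samples gave a camera p as small, so the call with 1 surrogate variable does not decide against the within-group axis. Chance is not excluded: 7 of 100 splits gave a camera p as small (3.05e-12, smallest other 6.39e-20). The treatment remains a possible explanation, untested beyond these values.

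Smooth muscle and pericyte genes were called lower as a list with chemotherapy than with tumor alone. The list stayed called with only the VM libraries (adjusted p = 2.72e-06) and with 1 surrogate variable (adjusted p = 6.5e-07; 1.05e-07 to 1.62e-05 over its alternatives in scaling, filter and samples), but not with an estimated correlation (adjusted p = 0.0998), and 1 of 100 splits, the real one, gave a camera p as small (3.52e-08, smallest other 6.3e-07), but the list was picked out of 39 and the splits make no allowance for that, so chance is not excluded. A smaller share of vessel in the piece of muscle would lower endothelial markers as far, and the smooth muscle minus endothelial score was lower with chemotherapy (-0.239 ± 0.107 against 0.120 ± 0.161, SD, exact permutation p = 0.00216, 6 of 6 samples below the tumor median), though without tumor library 10 the endothelial list was called lower too (adjusted p = 0.0381). A smaller share of large, smooth muscle-rich vessels, and of connective tissue, whose lists were also called lower, may still account for it. Those lists, matrix and fibroblast, lost their calls with an estimated correlation (adjusted p = 0.76 and 0.611) and with 1 surrogate variable (adjusted p = 0.142 and 0.125). An effect of the treatment on these cells is a hypothesis found and tested on the same data.

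Chance is not excluded for the other counts either. Between tumor and healthy samples the real count of called genes was 0, which every split had to reach, so that count decides nothing (highest other 3233). Of the 100 splits, 42 called as many lists (8, highest other 13) and 11 gave as many genes at an unadjusted p below 0.05 (2134, highest other 4824). The split that called 3233 genes points to a structure of the samples. Between chemotherapy and healthy samples 72 splits called as many lists (5, highest other 17). Between chemotherapy and tumor samples the real count of called genes was 0 too, so it decides nothing either (highest other 1). There 25 of 100 splits called as many lists (12, highest other 17) and 17 gave as many genes at an unadjusted p below 0.05 (685, highest other 1981).

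Single samples far from the rest of their group were found in 27 of 432 groups of values tested, where chance gives 21.6. In healthy samples Cep290 was at 12.4 CPM in library 2 (others 1.70 to 2.09), Cxcl14 at 90 in library 3 (37.6 to 52.7) and Hist1h2bo at 33.3 in library 4 (4.12 to 12.1). In healthy library 1 the cell cycle score was -0.594 (others 0.101 to 0.234) and the FoxO and glucocorticoid score 0.166 (-0.0303 to 0.00800). In healthy library 5 the clock score was 0.314 (-0.255 to -0.122) and the heat shock score 0.296 (-0.161 to -0.105). In tumor library 8 epithelial and keratin genes summed to 97.5 CPM (1.52 to 2.76).

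Of the 27, 10 were in chemotherapy library 11, and most of them were matrix genes. That sample was made of 2 libraries and was also the only chemotherapy sample with the MB suffix. Col1a1 was at 8160 CPM (others 865 to 3120), Col12a1 at 220 (63.6 to 111), Eln at 32.5 (12.8 to 18.4), Fmod at 408 (92.2 to 173), Thbs4 at 493 (172 to 233) and Tnc at 75.3 (19.9 to 29.1). Cdkn1a was at 31.2 (6.85 to 14.9), Socs3 at 8.16 (2.42 to 4.56) and Hist2h2aa3 at 3.37 (1.14 to 1.83), and the myostatin, activin and TGF-beta score was 0.213 (-0.143 to -0.104). Chemotherapy library 17 had B and plasma cell genes at a sum of 140 CPM (1.87 to 3.62), T and NK cell genes at 78.1 (20.6 to 28.4) and a class II score of 1.36 (-0.604 to 0.0711). It also had Thrsp at 67.3 (3.05 to 15.1), Cdo1 at 44.5 (4.54 to 17.5) and Fras1 at 23.8 (28.6 to 30.6). Fbxo32 was at 454 in library 15 (209 to 299), Hbb-bs at 24.0 in library 16 (5.30 to 11.8), and the oxidative phosphorylation score was 0.231 in library 13 (0.0195 to 0.0922).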

How the results depend on the processing

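The fits with libraries 11 and 12 apart, with the suffix as a term, with only the VM libraries and without healthy libraries 1, 3 and 4 were chosen after the data were seen, and the others were planned. Of the values of named genes under the planned choices, 2059 kept direction and side of the threshold, 308 lost and 55 gained a call and 37 turned with no call on either side. For lists these were 1954, 92, 71 and 163, and 6 turned with a call. Under the added ones 355 values of genes kept both, 122 lost a call, none gained one and 23 turned with no call. For lists 349 kept both, 26 lost and 17 gained a call, 67 turned with no call and 9 with one. The slow-fiber, ribosomal, smooth muscle, immediate early and clock lists kept their calls between chemotherapy and tumor under every alternative scaling, filter and set of samples, but all lists lost theirs with an estimated correlation. Small effects were often missed in simulation: at these depths and group sizes, 1.5-fold changes were recovered for 5 of 48 genes between tumor and healthy samples. The simulations lack the library differences shared across genes, so they do not give the power in the real samples.

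The choices of pseudocount and filter planned for normalized values were not run, because the table held counts, and lists were not tested with DESeq2 or limma-voom. Except where stated, the cause was not tested. For tumor against healthy, the counts of genes were 13 higher and 50 lower with DESeq2, and 0 to 245 and 0 to 259 leaving out 1 library. Of 1 list higher and 7 lower, there were 0 and 0 with an estimated correlation and with fry, 4 lower at 5 CPM or more (fewer genes tested), and 2 higher with only the 2 groups. There were 5 higher with 1 surrogate variable, 4 with the suffix term, 2 with only the VM libraries (1 healthy), and 0 lower without healthy libraries 1, 3 and 4 (fewer samples). Leaving out 1 library gave 1 to 3 higher and 4 to 10 lower.

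For chemotherapy against healthy, with 865 higher and 760 lower, the counts were 1669 and 348 with total counts only, which moves the median log2 fold change of all genes to 0.12 (0.13 for tumor against healthy). They were 474 and 410 with no filter (more genes tested), 1407 higher with DESeq2 and 1564 with limma-voom. They were 0 and 0 with 1 surrogate variable (707 at an unadjusted p below 0.05), the suffix term (993), only the VM libraries (1050) and without healthy libraries 1, 3 and 4 (585). Leaving out 1 library gave 0 to 2024 higher and 0 to 1775 lower, with 0 without healthy library 1, 3 or 4 or chemotherapy library 13, 14 or 15. Of 0 lists higher and 5 lower, there were 0 lower with an estimated correlation, 1 with fry and 3 at 5 CPM or more. There were 2 higher with total counts, 6 higher and 3 lower with 1 surrogate variable, 1 higher with libraries 11 and 12 apart, 2 with the suffix term, and 1 higher and 2 lower without healthy libraries 1, 3 and 4. Leaving out 1 library gave 0 to 1 and 5 to 8.

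For chemotherapy against tumor, the genes were 3 lower with DESeq2, and 4 higher and 4 lower with 1 surrogate variable. The 8 were Smpd3, C1qb, C1qc and Fcna higher and Fras1, Flnc, Usp28 and Nr1d1 lower, named after their values were seen. Leaving out 1 library gave 0 to 3 lower, with 3 without tumor library 9. Of 4 lists higher and 8 lower, there were 0 and 0 with an estimated correlation, 0 and 1 with fry, and 4 lower with 1 surrogate variable. Leaving out 1 library gave 2 to 6 higher.

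Lists that turned, with adjusted p, were for tumor against healthy immediate early genes with 1 surrogate variable (0.0205) and with the suffix term (0.00846). With the suffix term FoxO targets (0.0280), matrix (0.945) and heat shock (0.0228) turned. With only the VM libraries slow-fiber (0.976), fast-fiber (0.929), lipid synthesis (0.0497) and heat shock (0.00355) turned. For chemotherapy against healthy, fibroblast (0.887), complement (2.82e-06), macrophage (5.71e-08), Schwann cell (0.00904) and histone (0.606) lists turned with 1 surrogate variable, and slow-fiber (0.0181) with only the VM libraries.

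With total counts 7 list scores had an exact permutation p below 0.05 for tumor against healthy in place of 3, and 2 an adjusted p below 0.05 for chemotherapy against healthy in place of 0. The first component held 44.7% over all genes. With the healthy libraries split, the overlap fell to a correlation of 0.513, a covariance of 0.134 and 70.1% of genes with the same sign.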

Other observations

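The comparison of unnamed entries was chosen after the data were seen. The 5 lists with too few measured members were read as values. Mitochondrially encoded transcripts, 13 genes, had 0 counts in all libraries, which in muscle, where these transcripts are abundant, is not read as absence. Neutrophil markers (16 genes) summed to between 0.311 and 7.58 CPM over all samples. T and NK cell markers (19 genes) summed to between 19.8 and 45.3 CPM in healthy and tumor samples, and B and plasma cell markers (13 genes) there to between 2.45 and 7.55 CPM. Epithelial and keratin genes (20 genes) summed to between 1.21 and 5.69 CPM in all samples but tumor library 8.

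The unnamed entries left out of the tests held 0.245% of counts in healthy, 0.172% in tumor and 0.137% in chemotherapy samples on average. The share differed between chemotherapy and healthy samples (exact permutation p = 0.0303) in the same direction as the small noncoding RNA genes.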
